A study of Bacillus subtilis subsp. subtilis str. 168 with 12 samples.

How the data were processed

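Total RNA (20 microgram per labelling) from 3 independent preparations per comparison was converted to cDNA and labelled with Alexa Fluor 555 or 647, per the labels' protocols, and hybridised to spotted arrays of Bacillus subtilis. The deposited array files held the foreground and background median intensity of each spot in both channels, per the file headers. The authors also deposited background-subtracted intensities, their average over duplicate spots and a fold change of these averages, a ratio used here only to check directions. On 7 arrays the product of both channel maxima equalled the squared full scale within 1 percent, so the channels appear to have been rescaled against each other before deposit; how was not given in the sources used here. Between 1 and 6 spots per channel lay at the channel maximum. The deposited column definitions give the mutant the same channel throughout, which contradicts the labels of swapped arrays, and name vancomycin treatment as another use of that channel. The labels name no drug treatment, and they were used for strains and dyes.

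The deposited value table held log2 values. At least 99.9% of the values in each column, rounded to 4 decimals, occurred among the log2 of the deposited fold column of the same array. It held 0 values below 0, and between 28.6% and 68.7% of its cells were empty. Its column medians, in the order replicate 1, 2, 3 and dye swap, were 1.85, 0.51, 4.36 and 0.38 for delta MWX with WT, 0.52, 0.44, 0.41 and 2.99 for delta 7ECF with delta MWX, and 3.40, 3.20, 3.59 and 0.30 for delta 7ECF with WT. Its values are not centred, its rows carry no gene name and its negative side is missing, so it was not used for tests.

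Background was corrected with normexp on local background (offset 50) in limma 3.58.1 (R 4.3.3). Loess was fitted within each array on the gene spots, with control spots at weight 0. Each array had 8448 spots, including 192 blanks and 44 spots of 22 non-Bacillus oligonucleotides. The log2 ratios of the 2 spots of a gene were averaged and turned to the numerator strain by the dyes in the labels. The 2 arrays of replicate 3 of delta MWX with WT were averaged as 1 replicate. The scan filed under both delta 7ECF comparisons was left out of both, so there replicate 3 was the array not marked as a swap. This departs from the design, in which each swap was averaged with its partner, and was decided after the repeat was found; the design as written is among the alternatives.

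The 9 replicate ratios were fitted with 1 coefficient per comparison and a shared residual spread (lmFit and eBayes, 6 residual and 3.59 prior degrees of freedom). Each coefficient was tested against 0, two-sided, with Benjamini-Hochberg adjustment over 4106 genes and calls at an adjusted p under 0.05. The 33 gene lists were tested with camera (preset correlation 0.01), adjusted over all lists and the 3 comparisons, and again with an estimated correlation and with fry. Gene lists, tests, thresholds and the rule for named genes were fixed before the data were examined. The contrast between both mutants' ratios against WT, the detection level and the bounds below were not part of that design. Genes to name were the deleted sigma factor genes, up to 12 with the largest increase and 12 with the largest decrease per comparison among calls with the same sign in all 3 replicates, and up to 4 called members per list described. Where no gene passed, the 10 with the smallest p were to be named.

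Whether replicate numbers pair the samples was checked by correlating, across genes, the deviations of same-numbered replicates from their comparison's mean. Between delta 7ECF over WT and delta 7ECF over delta MWX all 3 correlations were positive (0.35 to 0.55). Between delta MWX over WT and delta 7ECF over delta MWX all 3 were negative (-0.33 to -0.19), the sign that a shared delta MWX extract would give. Between delta MWX over WT and delta 7ECF over WT they ran from -0.35 to 0.40. No dye term was used, and replicates 1 and 2 of these comparisons had opposite dye orientations. This range therefore does not tell whether WT extracts were shared. The labels do not say whether a number marks a shared extract, and a replicate block was run over all comparisons and over those with delta 7ECF only.

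A gene counted as well above background on an array where its mean foreground exceeded the 95th percentile of the non-Bacillus oligonucleotides in that channel. For a called gene below that level on every array of a strain, the fold is given as a bound from channel values after loess and Aquantile normalization, with the dim side of each array set no lower than its dimmest gene above background. Where the gene's own signal lay above that on all arrays, the fitted ratio is given and no bound. The bounds hold for the background correction used here: without it the fitted log2 ratio lay closer to 0 than the bound for 16 of the 18 called values with one. Such bounds can be biased by unbalanced dye orientation. Local background was no usable reference for this detection level in the Alexa 555 channel. There the median oligonucleotide spot minus local background lay between -761 and -44. The main fit still corrected that channel with normexp on local background, and background from oligonucleotide spots was run as an alternative. Gene names are those of the array; 3036 were current symbols in the RefSeq table of assembly ASM904v1 and 1070 were not. No coordinates are given because the files name no build.

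The fit was tested on simulated ratios for delta MWX over WT with 4106 genes, 200 of them changed. It recovered 69.0% of genes changed by 1 on the log2 scale, 95.5% of those changed by 2 and 100% of those changed by 4, and 4.79% of its calls were unchanged genes. The simulated noise was independent between genes and between replicates and held no dye effect. These rates therefore need not hold for the real arrays. Alternatives covered background, normalization, dim genes, the dye effect, use of the swaps, the design, a replicate block, thresholds, the prior and leaving out each replicate. Background from oligonucleotide spots, the repeated scan in delta 7ECF over WT only, a dye term on the replicate ratios, a replicate block in the delta 7ECF comparisons only and strain coefficients with a dye term were added after the data were seen.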

Results

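Transcript levels of the Gram-positive bacterium Bacillus subtilis were compared between a wild type (WT) and 2 deletion strains on 2-colour spotted arrays. Extracytoplasmic function (ECF) sigma factors are alternative subunits of RNA polymerase that direct it to promoters of genes of the cell envelope. By its name, and from what is known of the study, delta MWX lacks the genes of SigM, SigW and SigX, and delta 7ECF lacks those of all 7 ECF sigma factors, which adds SigY, SigV, SigZ and YlaC. Cultures were harvested at an OD600 of 0.4. Each of the 3 comparisons (delta MWX with WT, delta 7ECF with WT, and delta 7ECF with delta MWX) had 3 independent RNA preparations and 4 arrays, the last being a dye swap of replicate 3. The arrays carried 4106 genes in 2 spots each. Between 47.5% and 77.5% of genes were brighter than the non-Bacillus oligonucleotide spots in the Alexa 647 channel, and between 43.9% and 78.8% in the Alexa 555 channel. The number of arrays limits the precision.

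Of the 12 array files, 2 held identical intensities. They were filed as the dye swap of replicate 3 of delta 7ECF with WT and as that of delta 7ECF with delta MWX. This scan was left out of both comparisons, so 10 arrays entered the fit. Ratios were turned by the dyes in the labels, which name no drug treatment. For replicate 1 of delta 7ECF with WT the deposited fold column ran opposite to the labels' dyes, while it followed them on the other 11 arrays. Turned by the labels, the list of SigW genes had a median log2 ratio of -2.57 on that array. Replicates 2 and 3 had -1.60 and -1.96, which argues against reversed dyes in the label of replicate 1. Arrays of a comparison hybridised in the same dye orientation correlated across genes with r between 0.40 and 0.60, and those in opposite orientation with r between -0.0023 and 0.35 (genes are not independent replicates). The 3 usable arrays of delta 7ECF with delta MWX had 1 orientation, so strain and dye cannot be told apart within that comparison. In delta 7ECF with WT, replicate 1 had delta 7ECF RNA in Alexa 555 and replicates 2 and 3 had it in Alexa 647.

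**Figure D1:**
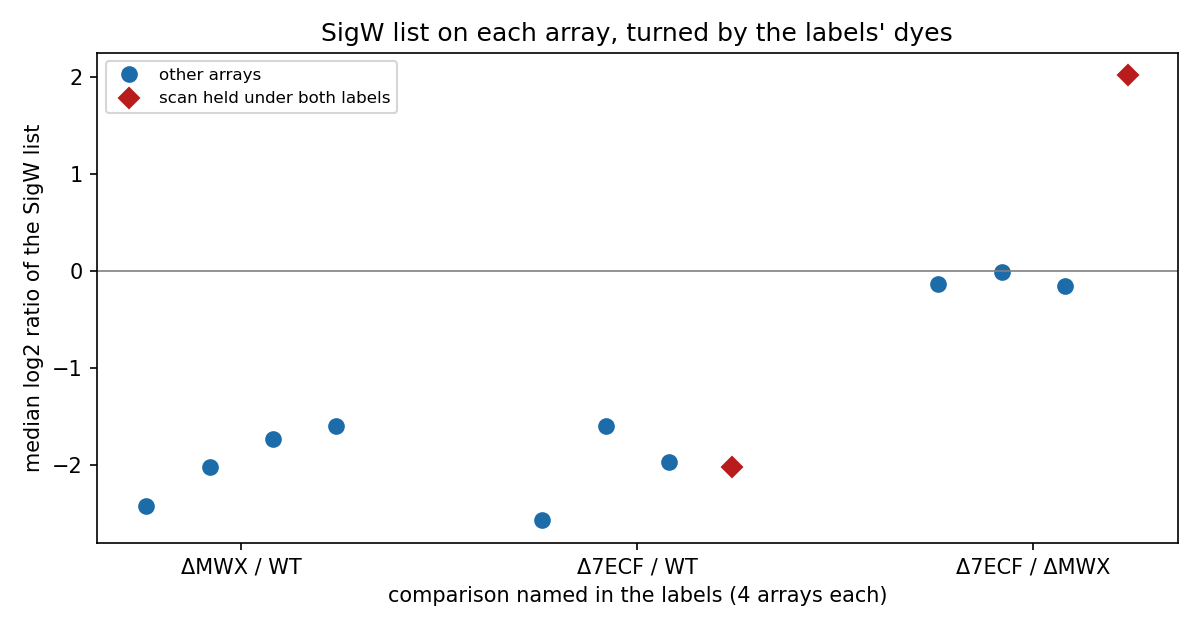
Median log2 ratio of the 53 measured genes of the SigW list (y axis) on each of the 12 arrays, grouped by the comparison in the labels (x axis), 1 point per array; diamonds mark the scan filed under both labels. As delta 7ECF over WT the scan lay at -2.02, and as delta 7ECF over delta MWX at 2.02, where the other 3 arrays lay between -0.16 and -0.011.

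The deleted genes were examined as a check of the labels. A probe outside the deleted part of a gene checks nothing, and where the probes lie was not given in the sources used here. In delta MWX over WT the log2 ratios (mean ± SD, n = 3) were -3.57 ± 0.88 for sigW (adjusted p = 0.0012), -2.81 ± 0.21 for sigX (adjusted p = 0.00015) and -1.75 ± 1.04 for sigM (adjusted p = 0.027). That of sigM was -0.997 without background correction, and it did not pass without replicate 1 (-2.04), without replicate 2 (-1.15) or without replicate 1 or 3 of delta 7ECF with delta MWX. In delta 7ECF over WT, sigX had -3.02 ± 0.64 (adjusted p = 9.1e-05). There sigW, sigY and sigM were not well above background with delta 7ECF RNA on any array. They were at least 24.6-fold lower (adjusted p = 0.00013), at least 6.02-fold lower (adjusted p = 0.0084) and at least 2.53-fold lower (adjusted p = 0.027), in that order. Without background correction the fitted log2 ratios of sigW, sigY and sigM were -4.16, -2.13 and -1.09, closer to 0 than these bounds. In delta 7ECF sigM passed neither without replicate 1, 2 or 3 of the comparison (-1.81, -1.39 and -1.81) nor without replicate 1 or 3 of delta 7ECF with delta MWX, and sigY passed neither without replicate 2 (-3.30) nor without replicate 3 (-2.76). The log2 ratios of sigZ (-0.52 ± 0.23) and ylaC (-0.88 ± 0.68) did not pass the threshold (adjusted p = 0.27 and 0.16), nor did sigV (adjusted p = 0.23), which was not well above background with delta 7ECF RNA. ylaC passed in 5 of 30 alternatives, among them 2 strain coefficients (adjusted p from 0.016 to 0.52 over all), and sigV in 1 of 28, median centring, while sigZ was at 0.026 with background taken from the oligonucleotide spots. The 7 genes as a list were called lower in both mutants by camera (adjusted p = 8.6e-07 in delta MWX and 6.7e-10 in delta 7ECF), and both calls held with an estimated correlation (adjusted p = 0.033 and 0.028). Since the list holds the deleted genes, these calls only check the labels. In delta MWX over WT sigY, sigV, sigZ and ylaC did not pass by limma (adjusted p = 0.97, 0.33, 0.86 and 0.81).

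**Figure D2:**
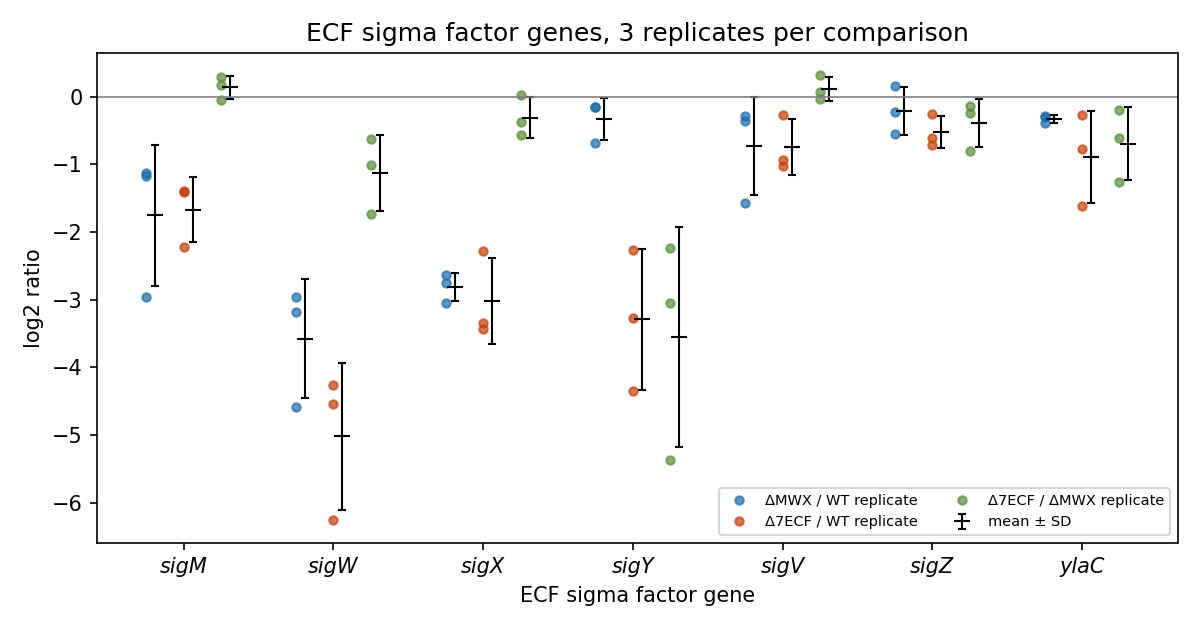
Log2 ratios of the 7 ECF sigma factor genes (x axis) in the 3 comparisons; coloured points are replicates, and black bars show the mean ± SD of 3 replicates. sigM, sigW and sigX lay below 0 in every replicate of both mutants over WT, and sigY lay at -0.33 ± 0.31 in delta MWX over WT. The points of genes not well above background are fitted ratios and no bounds, such as those of sigY in delta 7ECF over WT, where it was at least 6.02-fold lower.

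The comparison of delta MWX with WT asked which genes depend on SigM, SigW and SigX together. In delta MWX, 59 genes were lower and 10 were higher among 4106 tested by limma. The dlt operon, which attaches D-alanine to teichoic acids, was lower as a whole, with log2 ratios (mean ± SD, n = 3) of -4.72 ± 0.52 for dltA, -4.12 ± 0.03 for dltB and -3.74 ± 0.26 for dltD (adjusted p = 7.3e-06 for each). abh, a transition-state regulator related to AbrB, had -4.38 ± 0.51 (adjusted p = 8.8e-05). spo0M, a sporulation control gene, was not well above background in delta MWX and was at least 34.0-fold lower (adjusted p = 7.3e-06). racX, an amino acid racemase gene, was likewise at least 15.0-fold lower (adjusted p = 0.00011). Without background correction the fitted log2 ratios of spo0M and racX were -4.36 and -3.14, short of these bounds. yknW, also not well above background there, had a fitted log2 ratio of -3.97 ± 0.95 (adjusted p = 0.00079), which is no bound. ydjP and yknX had -3.86 ± 0.68 and -3.75 ± 0.77.

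Of the 53 measured members of the SigW list, 33 were lower and 0 higher, with 42 lower and 2 higher when adjusted over the list alone (median -2.33, camera adjusted p = 1.6e-57). Examples were yuaF (-5.15 ± 2.26, adjusted p = 0.011), yeaA (-4.31 ± 1.11, adjusted p = 0.0007) and yqeZ (-3.98 ± 0.40, adjusted p = 7.3e-05). Of 19 genes of the SigX list, 11 were lower, and 14 lower and 1 higher when adjusted over the list alone (median -1.40, camera adjusted p = 1.2e-22). All 5 genes of the dlt list, all of which the SigX list also holds, were lower (median -3.74, camera adjusted p = 5.9e-18). Of 46 genes of the SigM list, 4 were lower, and 18 lower and 1 higher when adjusted over the list alone (median -0.59, camera adjusted p = 1.4e-13). They included ywoA, which encodes an undecaprenyl pyrophosphate phosphatase (-2.55 ± 0.34), pbpX, which encodes a penicillin-binding protein (-2.74 ± 0.36), and yjbD (-1.63 ± 0.34). The SigM list lost its call with an estimated correlation (adjusted p = 0.22), while SigW, SigX and dlt held theirs (adjusted p = 0.028, 0.0021 and 0.028). Without replicate 2 the SigM median was -0.37. With plain background subtraction the SigW and SigX medians were -1.44 and -0.73, and both lists still passed by camera. yuaF and yjbD passed neither without replicate 1 (-4.38 and -1.59) nor without replicate 2 (-4.61 and -1.48).

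Of 6 genes for the bacteriocin sublancin, 4 were lower in delta MWX: bdbB (-2.88 ± 0.58), yolJ (-2.23 ± 0.82), the transporter gene sunT (-2.12 ± 0.71) and bdbA (-1.89 ± 0.62; mean ± SD, n = 3). The list's median was -2.01 (camera adjusted p = 9.3e-07, and adjusted p = 0.13 with an estimated correlation). All 19 genes of the biofilm matrix list had negative log2 ratios (median -0.78, camera adjusted p = 8.6e-12, and adjusted p = 0.22 with an estimated correlation). Of these only tasA, the matrix fibre protein gene, passed over all genes (-1.23 ± 0.40, adjusted p = 0.018), with 14 lower when adjusted over the list alone. Of the 10 genes that were higher, the largest log2 ratios were those of yrkO (2.29 ± 0.89), ylqB (1.97 ± 0.77), ctaE, a cytochrome oxidase subunit gene (1.78 ± 0.59), yyaK (1.55 ± 0.34), yhaP (1.51 ± 0.22) and yhaQ (1.46 ± 0.24). The others were wprA, a wall-associated protease gene (1.23 ± 0.44), yczI (1.21 ± 0.32), yvbJ (1.04 ± 0.42) and ytrB, a transporter gene (0.90 ± 0.13). tasA, sunT, yczI, yvbJ and ytrB lost their calls whichever replicate of the comparison was left out, yolJ, yhaQ and yrkO without replicate 1 or 2, ylqB and ctaE without replicate 2 or 3, and wprA without replicate 2, while their log2 ratios moved by at most 1.29 times. With no within-array normalization, which moved the median of all genes to -0.13, 1 gene was higher and 52 lower. Without replicate 1 of the comparison 6 genes were higher, without replicate 2 there were 2, and with the replicate number as a block 19 were higher (26 with a block in the delta 7ECF comparisons only).

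The comparison of delta 7ECF with WT asked the same of all 7 sigma factors. In delta 7ECF, 107 genes were lower and 11 higher by limma. The log2 ratios (mean ± SD, n = 3) of the dlt genes were -4.63 ± 0.26 for dltA (adjusted p = 9.3e-06), -3.78 ± 0.50 for dltB (adjusted p = 1.3e-05) and -3.74 ± 0.44 for dltD (adjusted p = 9.3e-06). abh had -4.11 ± 0.47 (adjusted p = 0.00011) and bdbB -4.04 ± 0.52 (adjusted p = 0.00021). Other genes were not well above background in delta 7ECF: yuaF was at least 24.6-fold lower (adjusted p = 0.008), yddK, a gene of the integrative element ICEBs1, at least 23.3-fold (adjusted p = 1.3e-05), spo0M at least 22.9-fold (adjusted p = 9.3e-06), yeaA at least 17.1-fold (adjusted p = 0.00053) and yknW at least 9.33-fold (adjusted p = 0.00083). Without background correction the fitted log2 ratios of these genes were -4.29, -4.30, -4.13, -3.73 and -2.88, in that order, short of the bounds. yuaF did not pass without replicate 2 (fitted log2 ratio -5.35).

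Of 53 SigW genes, 32 were lower in delta 7ECF, and 45 lower and 1 higher when adjusted over the list alone (median -1.98, camera adjusted p = 4.9e-47), among them yqeZ (-4.25 ± 0.84; SD, n = 3). Of 19 SigX genes, 15 were lower, the same number as adjusted over the list alone (median -1.54, camera adjusted p = 1.3e-20). All 5 dlt genes were lower (median -3.74, camera adjusted p = 5.8e-14). These 3 calls held with an estimated correlation (adjusted p = 0.033, 0.0021 and 0.033). Of 46 SigM genes, 7 were lower and 20 adjusted over the list alone (median -0.74, camera adjusted p = 2.6e-15, and adjusted p = 0.22 with an estimated correlation). pbpX and ywoA were not well above background in delta 7ECF. pbpX was at least 6.33-fold lower (adjusted p = 6.1e-05), and ywoA had a fitted log2 ratio of -2.18 ± 0.52 (adjusted p = 0.00038), which is no bound. Without background correction the fitted log2 ratio of pbpX was -2.18, short of its bound. Of 12 measured genes in the list for SigY, SigV, SigZ and YlaC, 6 were lower and 7 adjusted over the list alone (median -0.91, camera adjusted p = 1.9e-08, and adjusted p = 0.063 with an estimated correlation). pbpX is in this list too, and so are the neighbours of sigY, such as yxlD (-2.37 ± 1.12) and yxlE (-2.15 ± 0.91), and without genes beside the deleted ones its median was -0.53. Of 17 measured genes beside the deleted ones, 6 were lower and 8 adjusted over the list alone (median -0.48, camera adjusted p = 3.5e-06, and adjusted p = 0.11 with an estimated correlation). The median of that list was 0.25 with plain background subtraction, and that of the SigM list -0.46 without replicate 2. yxlD and yxlE passed neither without replicate 2 (-2.19 and -1.81) nor without replicate 3 (-1.91 and -1.98), and dltC neither without replicate 1 (-2.28) nor without replicate 2 (-2.59).

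Of the sublancin genes 4 of 6 were lower in delta 7ECF (median -2.57, camera adjusted p = 9.9e-06, and adjusted p = 0.16 with an estimated correlation), with sunT at -2.86 ± 0.58 (SD, n = 3). All 19 biofilm matrix genes had negative log2 ratios, and 6 passed, with 16 lower when adjusted over the list alone (median -1.01, camera adjusted p = 6.2e-15, and adjusted p = 0.18 with an estimated correlation). They included tasA (-1.55 ± 0.18) and, of the exopolysaccharide genes, yveL (-1.51 ± 0.67), yveR (-1.46 ± 0.39) and yvfE (-1.45 ± 0.58). Without background correction tasA had -1.02 and passed, while yveR had -0.85 and did not pass. pssA and psd, genes of phospholipid head groups, had -1.02 ± 0.33 and -0.97 ± 0.49, while their list of 23 fatty acid and phospholipid genes did not pass (camera adjusted p = 0.655). Of 46 motility and chemotaxis genes, 44 had positive log2 ratios (median 0.37, camera adjusted p = 2.5e-10, and adjusted p = 0.22 with an estimated correlation). Of these 1 passed, the chemoreceptor gene tlpB (1.02 ± 0.38), which had 0.18 and did not pass with no within-array normalization. Other genes that were higher included yrhP (1.95 ± 0.30), yczI (1.26 ± 0.53), yyaK (1.09 ± 0.37) and wprA (1.06 ± 0.30). hutH, a histidine degradation gene (1.42 ± 1.01), and leuC, of leucine synthesis (1.24 ± 0.67), were also higher, but without background correction they had 0.23 and 0.22 and did not pass. hisI, a histidine synthesis gene, had 0.93 ± 0.49 (adjusted p = 0.031), which turned to -0.077 without background correction. Without replicate 1 of the comparison 39 genes were higher and 71 lower, without replicate 2 there was 1 higher, and without replicate 3 there were 2 higher and 51 lower. Replicates 2 and 3 shared 1 dye orientation, so without replicate 1 strain and dye cannot be told apart in these counts. hutH, leuC, hisI, tlpB, wprA, yczI, yveL and pssA passed neither without replicate 2 nor without replicate 3, psd and yvfE neither without 1 nor without 3, yyaK neither without 1 nor without 2, and sunT and yveR not without 3, while their log2 ratios moved by at most 1.41 times. With no within-array normalization the median of all genes was -0.38, and 1 gene was higher, while with the replicate number as a block 18 were higher (45 with a block in the delta 7ECF comparisons only).

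**Figure D3:**
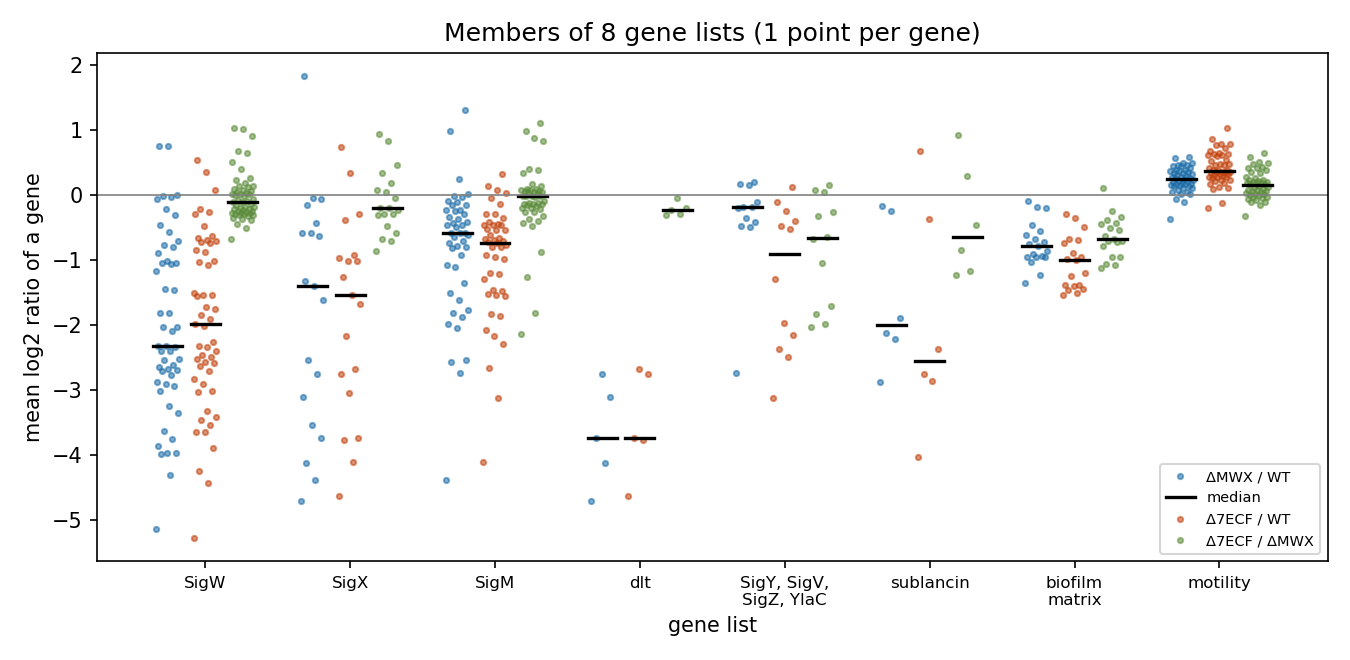
Mean log2 ratio of each measured gene (y axis, 1 point per gene) in 8 gene lists (x axis) and the 3 comparisons; black lines are list medians. The SigW medians lay at -2.33 in delta MWX over WT, -1.98 in delta 7ECF over WT and -0.12 in delta 7ECF over delta MWX.

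Of the 59 genes lower in delta MWX, 55 were also lower in delta 7ECF, where independent lists of these sizes would share 1.54. yyaK, wprA and yczI were the 3 genes higher in both, against 0.027. Across all genes the log2 ratios of both comparisons correlated with r = 0.62 and a covariance of 0.17. The labels do not state whether the same WT extracts served both comparisons. If they did, 100 simulations of unchanged strains gave r = 0.50, a covariance of 0.040 and 0.03 shared calls. By limma's test of the difference between both mutants' log2 ratios against WT only yddK passed (adjusted p = 0.00063), and 219 genes had an unadjusted p under 0.05, where chance gives 205.3.

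The direct comparison of delta 7ECF with delta MWX asked what loss of the other 4 sigma factors adds. In the fit with 1 coefficient per comparison yddK alone passed the threshold by limma: it was not well above background with delta 7ECF RNA and was at least 19.0-fold lower (adjusted p = 0.0002, lower in 3 of 3 replicates). Without background correction the fitted log2 ratio of yddK was -3.92, short of that bound. By limma 0 genes were higher. Of all genes 505 had an unadjusted p under 0.05, and 253 with a dye term, where chance gives 205.3. The usable arrays had 1 dye orientation, so the dye term also adds the error of its own estimate here. The fall in the count need not be removal of a dye effect alone. sigY, not well above background with delta 7ECF RNA, had a bound of at least 6.83-fold lower but did not pass (adjusted p = 0.071), nor did ylaC (log2 ratio -0.69 ± 0.54; SD, n = 3; adjusted p = 0.38). sigV and sigZ were not well above background in either strain (adjusted p = 0.84 and 0.38), so no ratio is given. The lists of SigW, SigX, SigM and dlt genes did not pass by camera (median log2 ratios -0.12, -0.20, -0.027 and -0.24; adjusted p = 0.66, 0.21, 0.54 and 0.31). The list for SigY, SigV, SigZ and YlaC was lower in delta 7ECF (median -0.67, camera adjusted p = 3.9e-05, and adjusted p = 0.13 with an estimated correlation), with 6 of 12 genes lower when adjusted over the list alone and 0 over all genes. Without the genes beside the deleted ones its median was -0.26 and it did not pass. Over the alternatives its median ran from -1.38 to -0.11, and it was -0.36 without background correction. The biofilm matrix list was lower (median -0.68, camera adjusted p = 5.2e-08, and adjusted p = 0.33 with an estimated correlation), with replicate medians of -0.30, -0.36 and -1.16. Its median was -0.34 without replicate 3, -0.17 with the repeated scan under both labels and -0.11 with no within-array normalization, which moved the median of all genes to 0.45. The 32 genes of the defective prophage PBSX had a median of 1.21 (camera adjusted p = 4.2e-13, and adjusted p = 0.38 with an estimated correlation), with replicate medians of 2.25, -0.48 and 1.97, and its median was 0.74 without replicate 1 and 2.13 without replicate 2. With the repeated scan used under both labels 0 genes were lower. There the scan, turned by the label of this comparison, brought in yddK at 5.77, and the fitted log2 ratio of yddK was -3.09. The call of yddK held in 28 of 29 alternatives. Using 2 strain coefficients for the whole triangle gave 7 higher and 27 lower (8 and 15 with a dye term). A replicate block in the delta 7ECF comparisons only gave 32 and 62, with sigY among the calls (limma adjusted p = 0.0026). Without replicate 1 of delta 7ECF with WT, whose spread the fit shares, 9 genes were lower and 1 higher, and without replicate 3 of this comparison 1 was higher. The former left delta 7ECF with WT with arrays of 1 dye orientation.

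The 3 comparisons form a triangle, so delta MWX over WT plus delta 7ECF over delta MWX was tested against delta 7ECF over WT. limma called 0 genes departing from that sum, with 94 at an unadjusted p under 0.05, fewer than the 205.3 that chance gives. Across genes the direct log2 ratio correlated with the indirect difference with r = 0.40. The departures had an SD over genes of 0.52, and the indirect difference had 0.47. The absence of calls therefore does not show that the ratios add up.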

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

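All tests of explanations in this part were chosen after the results had been seen, and the test of the difference between both mutants' log2 ratios against WT was not in the design. By that test yddK differed by -6.33 on the log2 scale (delta 7ECF over WT minus delta MWX over WT, limma adjusted p = 0.00063), a fitted value and no bound, since yddK was not well above background with delta 7ECF RNA. By camera's preset correlation 16 of the 33 lists differed. The median difference was negative for the deleted sigma factor genes (-0.32), the genes beside them (-0.56), the list for SigY, SigV, SigZ and YlaC (-0.62), cannibalism toxins (-0.47), biofilm matrix (-0.28), heat shock (-0.31), ribosomal proteins (-0.063) and ICEBs1 (-0.16). It was positive for motility (0.16), SigB general stress (0.22), Fur (0.29), purine and pyrimidine operons (0.25), branched-chain amino acid and CodY targets (0.27), arginine and histidine genes (0.41), PBSX (1.16) and SPbeta (0.29). The camera adjusted p ran from 9.6e-11 for PBSX to 0.027 for heat shock, and with an estimated correlation 0 of these lists passed (adjusted p from 0.13 to 0.61).

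The scan filed under both labels holds data outside the comparisons. Turned as delta 7ECF over WT, its SigW list had a median log2 ratio of -2.02, where the 3 replicates of that comparison had -2.04 ± 0.49 (SD). Turned as delta 7ECF over delta MWX it was 2.02, where the replicates had -0.10 ± 0.08, which argues against RNA of these 2 strains under the labels' dyes. yddK was at -5.77 in the scan as delta 7ECF over WT. So turned, the scan correlated across genes with replicates 1, 2 and 3 of that comparison with r = 0.66, 0.10 and 0.40. With replicate 3 of delta 7ECF over delta MWX r was 0.71. The scan so turned shared its dye orientation with that array and with replicate 1 of delta 7ECF over WT. Replicates 2 and 3 of delta 7ECF over WT had the opposite orientation. The correlations thus went with dye orientation and do not settle which RNA the scan holds. A candidate explanation is that the scan holds delta 7ECF and WT RNA and was filed under the other comparison in error; no biological explanation was tested.

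The log2 ratios of delta 7ECF over delta MWX came from arrays of 1 dye orientation. Across genes their mean correlated with r = -0.57 with the dye effect estimated from the other 2 comparisons, so a gene-specific dye effect may account for part of them. In the fit with a dye term 380 genes passed the threshold for dye. With background from the oligonucleotide spots the spread of the dye effect was 1.26 times as large. The choice of background changes the size of log2 ratios whatever their source. Whether local background set too high in the Alexa 555 channel is a source of the dye effect therefore stays open. With the dye term 0 genes were higher and 1 lower between the strains, yddK (fitted log2 ratio -5.26, adjusted p = 0.0011), while for other genes a difference between the strains stays open.

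In delta 7ECF over WT 3 of 23 ICEBs1 genes were lower (yddK, yddM and ydcN). ydcN lost its call whichever replicate of the comparison was left out, and without background correction (-0.83). The list had a median of -0.20 (camera adjusted p = 0.0014, and adjusted p = 0.10 with an estimated correlation). Over the alternatives its median ran from -0.67 to -0.086. Of the 3 genes above background with WT RNA on all 3 arrays (yddM, ydcL and yddK), 0 were so with delta 7ECF RNA on all 3, as loss of the element would give. But ydcL was so on 1 of these arrays, and its log2 ratio of -0.64 did not pass (limma adjusted p = 0.40). Against delta MWX, ydcL, yddE and yddF were above background with delta 7ECF RNA on all 3 arrays (yddE and yddF on 0 of 3 with delta MWX RNA). Those arrays had 1 dye orientation, so loss of the element is neither shown nor excluded. Medians of 10000 random sets of 3 genes of like brightness had a central range of -0.62 to 0.45. Such genes thus did not in general shift as far as yddM and yddK. The median of yddM, ydcL and yddK, -2.09, lay at percentile 0. But yddM and yddK were called lower beforehand and had prompted the comparison, so this rank was fixed in advance and tests nothing. The median of -2.09 is the value of yddM, which was -1.21 without background correction. With a dye term yddM had -2.16, again the median of the 3 genes, and yddK had -5.71. This argues against a gene-specific dye effect for these 2 genes, and not for the other genes of the element. Dependence on a sigma factor that only delta 7ECF lacks may also account for the pattern and was not tested.

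For each comparison 1 of the 4 assignments of signs to the replicates, the real one, gave as many genes, and 4 splits are too few for a share under 0.05. The real counts were 69 for delta MWX over WT, 118 for delta 7ECF over WT and 1 for delta 7ECF over delta MWX, and the highest of the others was 0 each time.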

How the results depend on the processing

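Chosen after the data were seen were the dye term on replicate ratios, strain coefficients with a dye term, background from oligonucleotide spots, a replicate block in the delta 7ECF comparisons only, and the repeated scan in delta 7ECF over WT only. Counts are given as higher and lower, in the order delta MWX over WT (comparison 1; 10 and 59), delta 7ECF over WT (comparison 2; 11 and 107) and delta 7ECF over delta MWX (comparison 3; 0 and 1). Only counts that moved by over 1.5 times are given, and the cause was not tested. Without background correction comparison 3 had 1 and 2. Plain subtraction gave 3 and 30 in comparison 1 and 7 and 52 in comparison 2, with 2643 genes missing a ratio. Background from oligonucleotide spots gave 2 lower in comparison 3. Median centring gave 17 higher in comparison 2 and 2 lower in comparison 3. No normalization gave 1 higher in comparisons 1 and 2. Arrays with duplicateCorrelation gave 25 higher in comparison 1, 49 and 176 in comparison 2 and 1 higher in comparison 3, and with a dye term 18 higher in comparison 1. Replicate 3's forward array alone gave 16 higher in comparison 1. The repeated scan under both labels left 0 lower in comparison 3; in delta 7ECF over WT only, it gave 7 higher in comparison 2 and 1 and 2 in comparison 3. Strain coefficients gave 44 and 99, 28 and 163, and 7 and 27, and with a dye term 49 and 114, 67 and 183, and 8 and 15. Each comparison alone gave 3 and 37 in comparison 1 and 2 and 48 in comparison 2. A 2-fold minimum left 7 higher in comparison 2. An adjusted p under 0.01 left 6 higher in comparison 1 and 1 and 61 in comparison 2. Trend and robust priors gave 4 higher in comparison 1 and 1 and 69 in comparison 2.

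Leaving out each replicate gave 2 to 14 and 40 to 64 in comparison 1, 1 to 39 and 51 to 106 in comparison 2, and 0 to 1 and 1 to 9 in comparison 3. Of delta MWX with WT, 6 were higher without replicate 1 and 2 without replicate 2. Of delta 7ECF with WT, there were 39 and 71 without replicate 1 (with 1 and 9 in comparison 3), 1 higher without replicate 2, and 2 and 51 without replicate 3. Leaving out its replicate 1 left delta 7ECF with WT with arrays of 1 dye orientation. Without replicate 3 of delta 7ECF with delta MWX 1 was higher there. Ratio closure called 0 genes in all alternatives in which it was run. The lists past the threshold numbered 17, 17 and 13 in comparisons 1 to 3. They were 6, 7 and 2 with plain subtraction, 4, 4 and 0 with an estimated correlation, 10 and 5 in comparisons 1 and 3 with fry, and 13 to 17, 14 to 18 and 13 to 15 with a replicate left out. Of 89 called values of named genes 22 kept direction and call in every alternative run, and of 47 list calls 8 did.

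The value of hisI, delta 7ECF over WT, turned to -0.077 without background correction and to -0.00198 with oligonucleotide background, and that of sigZ, delta 7ECF over WT, to 0.026 with the latter. That of sigV, delta 7ECF over delta MWX, turned to -0.076, -0.10 and -0.12 without background correction, with oligonucleotide background and with median centring. With plain subtraction the genes beside the deleted ones turned to 0.25 in comparison 2, and SPbeta to -0.055 in comparison 3. Other list medians changed sign where the list test did not. With no normalization, which moved the median of all genes to -0.13, -0.38 and 0.45 in comparisons 1 to 3, they were purine and pyrimidine (-0.10), branched-chain (-0.21) and arginine and histidine genes (-0.0021) in comparison 2, envelope two-component targets (0.21), cannibalism toxins (0.049) and ICEBs1 (0.095) in comparison 3, and envelope targets in comparison 1 (-0.011; -0.0022 without background correction). Wall synthesis in comparison 2 had 0.037 with plain subtraction and 0.059 with median centring, and in comparison 3 purine and pyrimidine operons had -0.025 with plain subtraction and Fur -0.0036 with the repeated scan under both labels. With a replicate left out, ribosomal proteins in comparison 1 ran from -0.00013 to 0.23, envelope targets in comparison 1 from -0.049 to 0.21, and purine and pyrimidine operons in comparison 3 from -0.0024 to 0.52.

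Replicate numbers showed no pairing common to all 3 comparisons, and 8 of 18 correlated best with their own number. Same-numbered replicates of comparisons 2 and 3 deviated together (r = 0.35 to 0.55). Those of comparisons 1 and 3 deviated in opposite directions (-0.33 to -0.19), the sign a shared delta MWX extract would give. The check held no dye term, and replicates 1 and 2 of comparisons 1 and 2 had opposite dye orientations. It therefore cannot tell whether comparisons 1 and 2 shared WT extracts. The replicate block over all gave 19 higher in comparison 1, 18 higher in comparison 2 and 2 lower in comparison 3. The block in comparisons 2 and 3 only gave 26 higher in comparison 1, 45 higher in comparison 2, and 32 and 62 in comparison 3. A block takes variation shared by same-numbered replicates out of the error of a test against 0, so these counts do not allow for variation between shared extracts. Not run were bad-spot flags, as no flag was used here, the median of spots, equal to the mean for 2 spots, renormalization of normalized values, and the value table. duplicateCorrelation without the repeated scan could not be estimated, and list tests were not run on array-level fits or with trend and robust priors. Signal over background limits dim genes: up to 60.6% of spots were at or below local background in the Alexa 555 channel.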

Other observations

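All lists in this part were fixed beforehand, and 0 of the calls given here held with an estimated correlation. In delta MWX over WT the skf and sdp cannibalism toxin genes had a median log2 ratio of 0.61 (camera adjusted p = 0.00025, and adjusted p = 0.22 with an estimated correlation), with 4 of 11 genes higher when adjusted over the list alone and 0 over all genes, and a median of 0.35 without replicate 2. Motility genes had a median of 0.25 and replicate medians of -0.022, 0.46 and 0.30 (camera adjusted p = 1.4e-06, and adjusted p = 0.33 with an estimated correlation), and a median of 0.11 without replicate 2. The SPbeta prophage had a median of -0.27 over 182 genes (camera adjusted p = 1.3e-10, and adjusted p = 0.13 with an estimated correlation), and its 4 called members were the sublancin genes bdbB, bdbA, sunT and yolJ. The SPbeta median was -0.15 without background correction, and -0.037 with plain background subtraction, where the list did not pass. SigB general stress genes had a median of -0.23 (camera adjusted p = 0.0014, and adjusted p = 0.38 with an estimated correlation), which was -0.15 and did not pass without replicate 1. PBSX genes had a median of -0.93 (camera adjusted p = 8.2e-08, and adjusted p = 0.54 with an estimated correlation).

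In delta 7ECF over WT, purine and pyrimidine genes had a median of 0.31 (camera adjusted p = 0.001), arginine and histidine genes 0.40 (camera adjusted p = 0.00051), branched-chain amino acid and CodY genes 0.41 (camera adjusted p = 0.0044) and Fur-regulated iron uptake genes 0.31 (camera adjusted p = 0.001). With an estimated correlation the adjusted p were 0.54, 0.38, 0.22 and 0.57. The medians of replicates 1, 2 and 3 were 0.58, 0.22 and 0.28 for purine and pyrimidine genes, 0.11, 0.30 and 0.98 for arginine and histidine genes, 0.11, 0.068 and 0.89 for branched-chain amino acid genes, and -0.22, 0.50 and 0.63 for Fur-regulated genes, of which replicate 1 thus had the opposite sign. With no within-array normalization, where the median of all genes was -0.38, the medians of the first 3 lists turned to -0.10, -0.0021 and -0.21, while camera called them higher than other genes. The calls were lost without replicate 1 for purine and pyrimidine genes (median 0.21), and without replicate 3 for arginine and histidine genes (0.059), branched-chain amino acid genes (0.13) and Fur-regulated genes (0.15).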
